A study of Homo sapiens with 6 samples.

How the data were processed

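Poly(A) RNA of LX-2 cells was sequenced as paired-end libraries, 3 from cells given a non-targeting control siRNA and 3 from cells labelled as given an ATP6AP1 siRNA; groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with TRIzol, enriched on oligo(dT) beads, fragmented and copied with random hexamers. The submitters' processing notes name FastQC, Trimmomatic, HISAT2, featureCounts, DESeq2 and the GRCh38 (hg38) genome, without versions or roles. The annotation release, the strand setting and the treatment of multiply mapping reads are not given in the sources used here.

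The authors deposited 1 table of 32750 Ensembl gene IDs in 6 columns, whose values are estimated counts (expected counts), since 12.3 to 13.9% of the genes in a library held a value that was not whole. Whole-number counts had been assumed when the tests were fixed; the values were therefore rounded to whole numbers for the count model, and the unrounded values were run as an alternative. How a table with fractional values came from the tools named in the notes is not given in the sources used here. Symbols, coordinates and gene spans came from GENCODE release 44 (GRCh38), in which 21947 IDs had a symbol; the 10803 others held 0.691 to 0.843% of the counts of a library and stayed in the totals and tests.

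Total counts per library ran from 15644464 to 19656533. A count-based interval covers counting error only, and errors given are the SD over 3 libraries or the SE of the fit. Replicate libraries differed by more than sampling noise (chi-square per gene 3.46 to 8.89 within groups, 47.3 to 54.1 between), so none was a duplicate of another. TMM factors were 0.958, 0.949 and 0.953 in the control libraries and 1.06, 1.05 and 1.04 in the libraries labelled ATP6AP1 siRNA.

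Genes were kept with filterByExpr (15372 tested) and compared with edgeR 4.0.16's two-sided quasi-likelihood F test in R 4.3.3, TMM normalisation, group as the model's term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The common dispersion was 0.00475, a biological coefficient of variation of 6.89%. The labels give no batch or day. CPM values are normalised with the TMM factors. The 35 gene lists (27 pathway, 3 RNA quality, 5 other cell type) were written before the data were examined; the 31 with at least 5 tested members were compared by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, Benjamini-Hochberg over lists. ATP6AP1 itself is in no list.

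Alternatives were DESeq2's size factors in edgeR, library size alone, no filter, a filter of 5 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, the replicate number as a block, each replicate left out in turn, an adjusted p of 0.01, a test against a fold of 1.2, and for lists camera with an estimated correlation and fry. Added after the data were seen were unrounded values and the removal of each library's trend on gene span, or on transcript length and GC content, as an offset.

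Named genes followed a rule fixed before the data were examined. They were ATP6AP1; the 10 raised and 10 lowered genes with the largest fold changes among those past the test with a mean of at least 5 CPM, a symbol and no overlap between groups; up to 4 members of each pathway or RNA quality list with the lowest adjusted p (2 as values where none passed); 22 genes fixed by name; and the 2 most abundant members of each list of another cell type. Of the 159 genes so named, 18 had over 30% of their 50-base windows in transcripts of other genes, and these are uncertain. Some of the genes named by the rule are not reported here.

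The steps were tested on simulated data, with counts drawn for the 15372 tested genes from the means and library sizes of this comparison. Of these, 15147 passed the filter, and a planted gene lost there would count as not recovered. Of 50 genes each, edgeR recovered 44% at 1.25-fold, 72% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 6.59% of its calls were false. Far fewer genes changed there than the 8193 called in the data. That makes the adjustment stricter, so these shares do not give the recovery in the data. Of 200 random lists, 3.5% had a camera p under 0.05 where genes were simulated independently, so that test does not cover correlated genes.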

Results

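RNA sequencing was carried out on LX-2 cells, an established human line of hepatic stellate cells, the liver cells that deposit collagen in fibrosis. There were 2 groups of 3 libraries: cells given a non-targeting control siRNA, and cells labelled as given an siRNA against ATP6AP1. The submitters call the 3 libraries of each group independent biological replicates. ATP6AP1 is an accessory subunit of the vacuolar proton pump (V-ATPase), which acidifies lysosomes and other compartments. The comparison asks which transcripts change when ATP6AP1 is depleted. The series title speaks of activated cells, but an activating treatment is not given in the sources used here. Total counts were 17749912, 19656533 and 17700222 in the control libraries and 15644464, 15854778 and 17880546 in the libraries labelled ATP6AP1 siRNA.

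The siRNA target itself was examined first. ATP6AP1 (ENSG00000071553, chromosome X, 154428633 to 154436516 on GRCh38, protein-coding) stood at 116, 117 and 129 CPM (read counts scaled to the normalised library size) in the control libraries. In the libraries labelled ATP6AP1 siRNA it stood at 144, 146 and 140 CPM, higher and not lower. The means were 121 ± 7.26 and 143 ± 3.01 CPM (SD, n = 3 each), a 1.19-fold difference with a 95% confidence interval from 1.08 to 1.30. The log2 fold change was 0.25 (SE 0.0608, edgeR with Benjamini-Hochberg adjustment, adjusted p = 0.00425). No copies of its sequence were found, as 0% of the 50-base windows of its transcript occur in transcripts of other genes. The mRNA of the target therefore goes against the label, and every direction given here is that of the libraries labelled ATP6AP1 siRNA against the control libraries, not of a measured depletion.

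**Figure D1:**
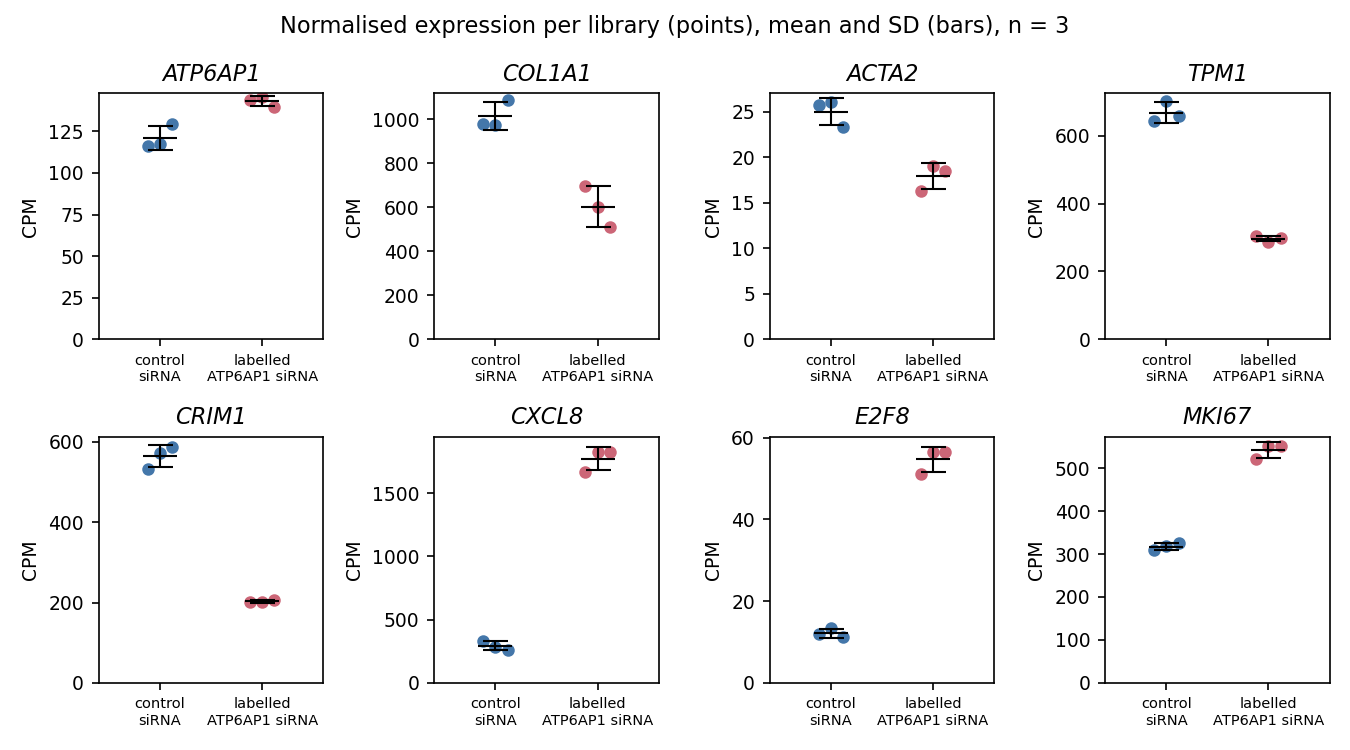
Normalised expression (CPM, linear axis from 0) of 8 genes in the 3 control libraries and the 3 libraries labelled ATP6AP1 siRNA; points are libraries, bars are the mean and SD. ATP6AP1 sat at 140 to 146 CPM in the libraries labelled ATP6AP1 siRNA and at 116 to 129 CPM in the controls, while COL1A1, ACTA2, TPM1 and CRIM1 were lower and CXCL8, E2F8 and MKI67 higher without overlap of the groups.

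In the libraries labelled ATP6AP1 siRNA, chemokines and inflammatory cytokines made up 6 of the 10 raised genes with the largest fold changes among those with a mean of at least 5 CPM over all libraries, with CXCL8, a neutrophil chemoattractant, going from 292 ± 35.9 to 1774 ± 91.0 CPM (SD, n = 3 each), 6.08-fold. Raised members outnumbered lowered ones among genes of DNA replication (23 against 2 of 30), mitosis (21 against 3 of 33) and p53 targets (18 against 1 of 25), and lowered ones outnumbered raised ones among collagens (14 against 1 of 17), other matrix genes (17 against 1 of 28), contractile genes (17 against 1 of 21) and targets of the transcriptional co-activators YAP and TAZ (21 against 2 of 24). None of these lists passed camera with an estimated correlation (in that order, adjusted p = 0.244, 0.396, 0.170, 0.396, 0.396, 0.396 and 0.321 with an estimated correlation). COL1A1, the alpha-1 chain of type I collagen, went from 1013 ± 64.1 to 602 ± 94.5 CPM, 1.68-fold lower. Genes of the lysosome and of the V-ATPase itself went both ways.

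Of 15372 genes tested, 8193 (53.3%) changed in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4110 raised and 4083 lowered. The split rests on the scaling: with library size alone and no composition factor, 5618 were raised and 2733 lowered, a shift of the median log2 fold change by 0.14. Such a shift falls on large and small changes alike, so in proportion it weighs most on small ones. With library size alone the log2 fold changes of ATP6AP1 and SQSTM1 went from 0.25 to 0.38 and from 0.26 to 0.39. Those of TFE3 and FTH1 went from -0.41 to -0.27 and from -0.40 to -0.26. Those of FTL, TIMP1 and TGFB1 went from -0.36 to -0.22, from -0.33 to -0.19 and from -0.38 to -0.24. A change of at least 2-fold was reached by 653 raised and 480 lowered genes, 1133 in all, and by 597 with a filter of 5 CPM in 3 libraries, which tests fewer genes (11591). The median absolute log2 fold change of the changed genes was 0.49. The values of the groups did not overlap in 9139 genes (59.5% of those tested; chance gives 10%). Correlations of log2 CPM across genes, which are not independent replicates, were 0.989 to 0.992 within groups and 0.969 to 0.972 between them, and the first principal component, with 66.2% of the variance, separated the groups.

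**Figure D2:**
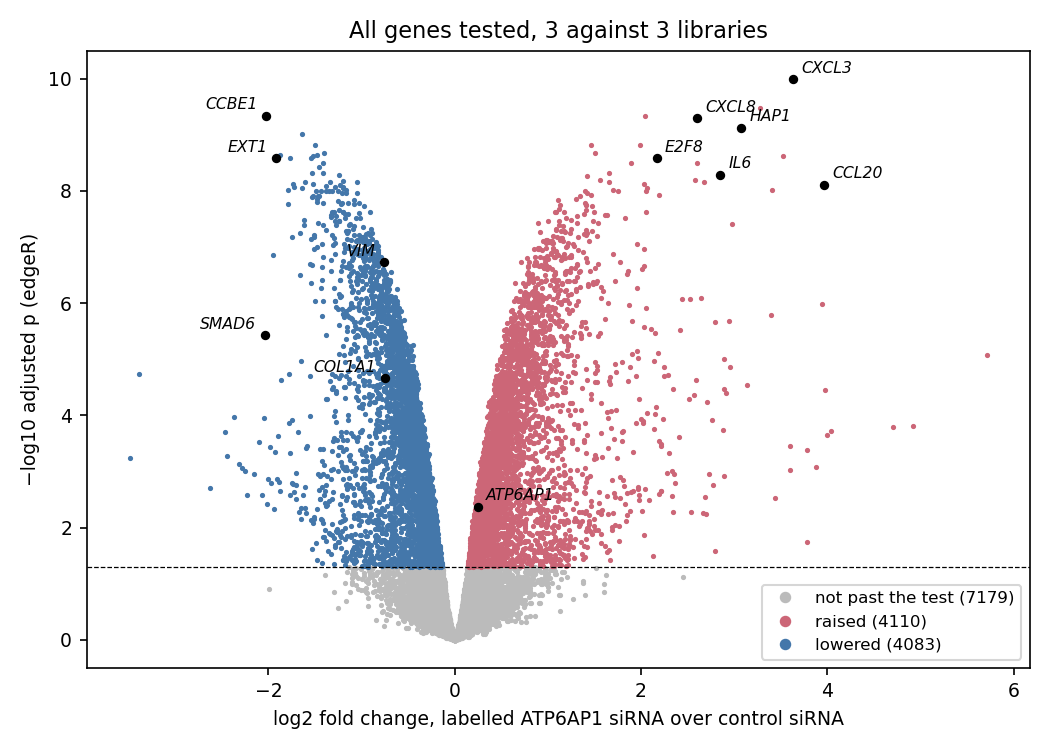
Log2 fold change (libraries labelled ATP6AP1 siRNA over control siRNA, 3 against 3) against the negative log10 of the edgeR adjusted p for the 15372 genes tested; red points are the 4110 raised, blue the 4083 lowered and grey those not past the test. ATP6AP1 itself lies at 0.25, on the raised side.

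By the rule for named genes, the 10 raised genes with the largest fold changes held 6 secreted inflammatory factors. CCL20 (ENSG00000115009, chromosome 2, 227805739 to 227817564), a lymphocyte chemokine, rose 15.6-fold from 1.34 ± 0.328 to 21.2 ± 3.55 CPM (SD, n = 3 each; edgeR adjusted p = 7.81e-09). CXCL3 (ENSG00000163734, chromosome 4, 74036589 to 74038807), a neutrophil chemokine, rose 12.4-fold from 7.22 ± 0.570 to 89.9 ± 6.17 CPM (adjusted p = 1.01e-10). CXCL2 rose 9.69-fold, IL6 7.20-fold (5.73 ± 1.24 to 41.5 ± 2.99 CPM, adjusted p = 5.17e-09), and CXCL8 (ENSG00000169429, chromosome 4, 73740519 to 73743716) 6.08-fold (adjusted p = 5.12e-10). CSF3, the granulocyte colony-stimulating factor, rose by 2.67 on the log2 scale. The other members, with their log2 fold changes, were RND1, a small GTPase (3.53), FOS, an AP-1 subunit (3.40), HAP1, the huntingtin-associated protein (3.08), and GADD45G, a stress-inducible gene (2.98).

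Among the 10 lowered genes of that rule, SMAD6, an inhibitory SMAD, was 4.11-fold lower (9.37 ± 1.69 to 2.29 ± 0.610 CPM, edgeR adjusted p = 3.76e-06). CCBE1 (ENSG00000183287, chromosome 18, 59430939 to 59697662), a secreted factor that promotes VEGFC processing, was 4.08-fold lower (190 ± 9.93 to 46.6 ± 0.370 CPM, adjusted p = 4.58e-10). VEGFC fell by 1.77 on the log2 scale, EXT1, a heparan sulfate polymerase, by 1.92, HAS2, a hyaluronan synthase, by 1.79, and ATP8B1, a phospholipid flippase, by 1.88. The nuclear receptor NR2F2 went from 616 ± 54.4 to 185 ± 17.4 CPM (log2 fold change -1.74). The RNA MIR503HG fell by 1.95. HIF1A-AS3 (-1.79) and KRTAP2-3 (-1.74) are uncertain, since 32.2% and 39.7% of their 50-base windows occur in other transcripts and HIF1A-AS3 lies antisense to HIF1A. CCBE1, EXT1, ATP8B1 and VEGFC span 267, 317, 157 and 109 kb, and the longest genes were lower as a group. Their log2 fold changes were at the weakest -1.64, -1.48, -1.66 and -1.64 over alternatives. Others of the 10 were short, such as MIR503HG at 3.52 kb and NR2F2 at 14.3 kb.

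Gene lists written before the data were examined were then compared, again in the libraries labelled ATP6AP1 siRNA, whose target was not lower. Of 31 lists with at least 5 tested members, 16 changed in camera with a preset correlation of 0.01 (Benjamini-Hochberg over lists), 5 raised and 11 lowered. None of the 31 passed camera with an estimated correlation (4 had an unadjusted p under 0.05), whereas 24 passed fry, which asks whether genes of a list move one way without comparing them with other genes. The 24 were the 16 called by camera and 8 more, whose fry adjusted p is given with each. Fry was run with the TMM factors alone, so its calls and directions rest on that scaling. Over alternatives the medians of the cholesterol, oxidative phosphorylation and V-ATPase lists crossed 0, to 0.032, 0.0057 and -0.0028. The medians of the others among the 8 kept their sign. Counts of members adjusted over the list alone equalled those over all genes except in 8 lists, where both are given. Where 5 or fewer members went against the rest they are named, having been chosen after their values were seen.

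Inflammatory cytokines and NF-kB targets had 25 of 30 tested members raised, 3 lowered (CXCL12, IL33 and TLR4) and 2 not past the test. Their median log2 fold change was 0.89 (camera adjusted p = 1.47e-07, adjusted p = 0.170 with an estimated correlation). Besides the chemokines already given, CXCL1 rose 4.12-fold, from 67.6 ± 3.94 to 279 ± 9.50 CPM. Of 28 interferon-stimulated genes, 14 rose, 3 fell (IFIT1, BST2 and IFIT5) and 11 did not pass (camera adjusted p = 0.0199, adjusted p = 0.346 with an estimated correlation). That call was lost, at an adjusted p of 0.0840, once the trend on gene span was removed, over a range up to 0.346, while the median log2 fold change went from 0.28 to 0.20. The transcription factors IRF1 and IRF7 rose by 1.42 and 2.03 on the log2 scale and the antiviral OAS3 by 0.78, while IFIT1 fell by 0.82.

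Of 30 DNA replication genes, 23 rose, 2 fell (CCND1 and MCM6) and 5 did not pass (camera adjusted p = 1.98e-06, adjusted p = 0.244 with an estimated correlation). E2F8, a repressor of the E2F family, went from 12.2 ± 1.12 to 54.7 ± 3.13 CPM (SD, n = 3 each; log2 fold change 2.17, edgeR adjusted p = 2.61e-09). E2F2 rose by 2.06, the origin-licensing factor CDC6 by 1.11 and MCM10 by 1.04. Of 33 mitosis genes, 21 rose, 3 fell (ANLN, CCNB1 and CCNA2) and 9 did not pass, and 23 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.00136, adjusted p = 0.396 with an estimated correlation). MKI67, the proliferation marker Ki-67, went from 317 ± 7.86 to 542 ± 18.3 CPM, a log2 fold change of 0.77. The kinesin KIF2C rose by 0.95 and UBE2C by 0.71, while the cytokinesis scaffold ANLN fell by 0.87. Of 25 p53 targets, 18 rose, BAX fell and 6 did not pass (camera adjusted p = 7.24e-05, adjusted p = 0.170 with an estimated correlation). CDKN1A, the cell cycle inhibitor p21, rose by 0.86, with BTG2 at 2.03, PLK3 at 1.13 and TP53I3 at 0.93. The median gene span of these raised lists was 9.94 kb for the inflammatory genes, 23.5 kb for the interferon-stimulated, 22.4 kb for replication, 29.4 kb for mitosis and 23.0 kb for p53 targets, against 30.8 kb over all tested genes.

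Collagens were lower in 14 of 17 tested members, with COL7A1 raised and 2 not past the test, and 15 were lower adjusted over the list alone (median log2 fold change -0.70, camera adjusted p = 5.62e-05, adjusted p = 0.396 with an estimated correlation). COL1A1 (ENSG00000108821, chromosome 17, 50184101 to 50201632) fell by 0.75 on the log2 scale (SE 0.0935, edgeR adjusted p = 2.15e-05). COL1A2 fell by 0.70, COL3A1 by 1.13, COL4A1 by 1.02, COL8A1 by 1.41 and COL11A1 by 1.51. Of 28 other matrix proteins and collagen-processing enzymes, 17 fell, PLOD1 rose and 10 did not pass (camera adjusted p = 7.24e-05, adjusted p = 0.396 with an estimated correlation). SPARC fell by 1.01, the laminin chain LAMC1 by 0.83 and the collagen cross-linking enzymes LOX and LOXL2 by 0.88 and 0.91. Fibronectin, FN1, had a log2 fold change of -0.15 and did not pass (edgeR adjusted p = 0.0636), though it did with no filter (0.0478) or without control replicate 1 (0.0452), over a range of adjusted p up to 0.916 across alternatives. Matrix-degrading proteases and their inhibitors were lower in 13 of 19, with ADAM17 and MMP19 raised and 4 not past the test (camera adjusted p = 0.000508, adjusted p = 0.396 with an estimated correlation). ADAMTS1 fell by 1.38, PLAT by 0.94, MMP15 by 0.99 and TIMP1 by 0.33.

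Contractile and cytoskeletal genes of myofibroblasts were lower in 17 of 21, with SMTN raised and 3 not past the test, and 2 raised and 17 lowered adjusted over the list alone (camera adjusted p = 7.24e-05, adjusted p = 0.396 with an estimated correlation). TPM1 fell by 1.17 on the log2 scale, the myosin kinase MYLK by 0.98, CALD1 by 0.83 and vimentin, VIM, by 0.76. ACTA2, smooth muscle actin and the usual marker of stellate cell activation, went from 25 ± 1.49 to 17.9 ± 1.43 CPM (log2 fold change -0.48, edgeR adjusted p = 0.000540). TAGLN fell by 0.54, a value that is uncertain because 65.5% of its 50-base windows lie in an overlapping transcript. YAP and TAZ targets were lower in 21 of 24, with NUAK2 and GADD45B raised and 1 not past the test (median log2 fold change -0.79, camera adjusted p = 2.37e-07, adjusted p = 0.321 with an estimated correlation). CRIM1 went from 565 ± 27.9 to 203 ± 3.68 CPM, tissue factor, F3, fell by 1.38, ASAP1 by 1.43, the DNA-binding partner TEAD1 by 1.06 and CCN2 by 0.68. With the gene span trend removed, the log2 fold changes of the long genes ASAP1, TEAD1, MYLK and CALD1 shrank to -0.93, -0.67, -0.59 and -0.49.

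Members of the TGF-beta pathway, the main fibrogenic signal of stellate cells, were lower in 16 of 28, with 5 raised (INHBA, ID2, BAMBI, PMEPA1 and TGFB3) and 7 not past the test (camera adjusted p = 0.0128, adjusted p = 0.346 with an estimated correlation). SMAD3 fell by 1.17, TGFB2 by 1.47, BMP4 by 1.39 and TGFB1 by 0.38. PDGF and other growth factors and receptors were lower in 12 of 19, with FLT1, HBEGF and KDR raised and 4 not past the test (camera adjusted p = 0.0239, adjusted p = 0.321 with an estimated correlation). PDGFC fell by 1.48, IGFBP5 by 1.24 and PDGFRB by 0.67, while HBEGF rose by 1.08. Genes of the quiescent stellate state did not pass camera as a list: 8 of 16 rose and 5 fell (RARB, RELN, PLIN3, GATA4 and RXRA), with a camera adjusted p of 0.486 and a fry adjusted p of 0.0167, toward higher. Among these, the nerve growth factor receptor NGFR rose by 2.58, GATA6 by 1.29, and BAMBI rose as well. The median gene span was 109 kb for collagens, 61.4 kb for other matrix genes, 21.1 kb for proteases, 29.3 kb for contractile genes, 53.7 kb for YAP and TAZ targets, 44 kb for the TGF-beta pathway and 69.0 kb for growth factors, and the longest genes were lower in the same libraries: of 1298 protein-coding genes in the longest decile by span, 773 fell and 92 rose. The relation was not even: the median log2 fold change was -0.030 in the shortest decile (0.11 with library size alone), 0.14 in the decile around 13.8 kb and -0.40 in the longest.

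**Figure D3:**
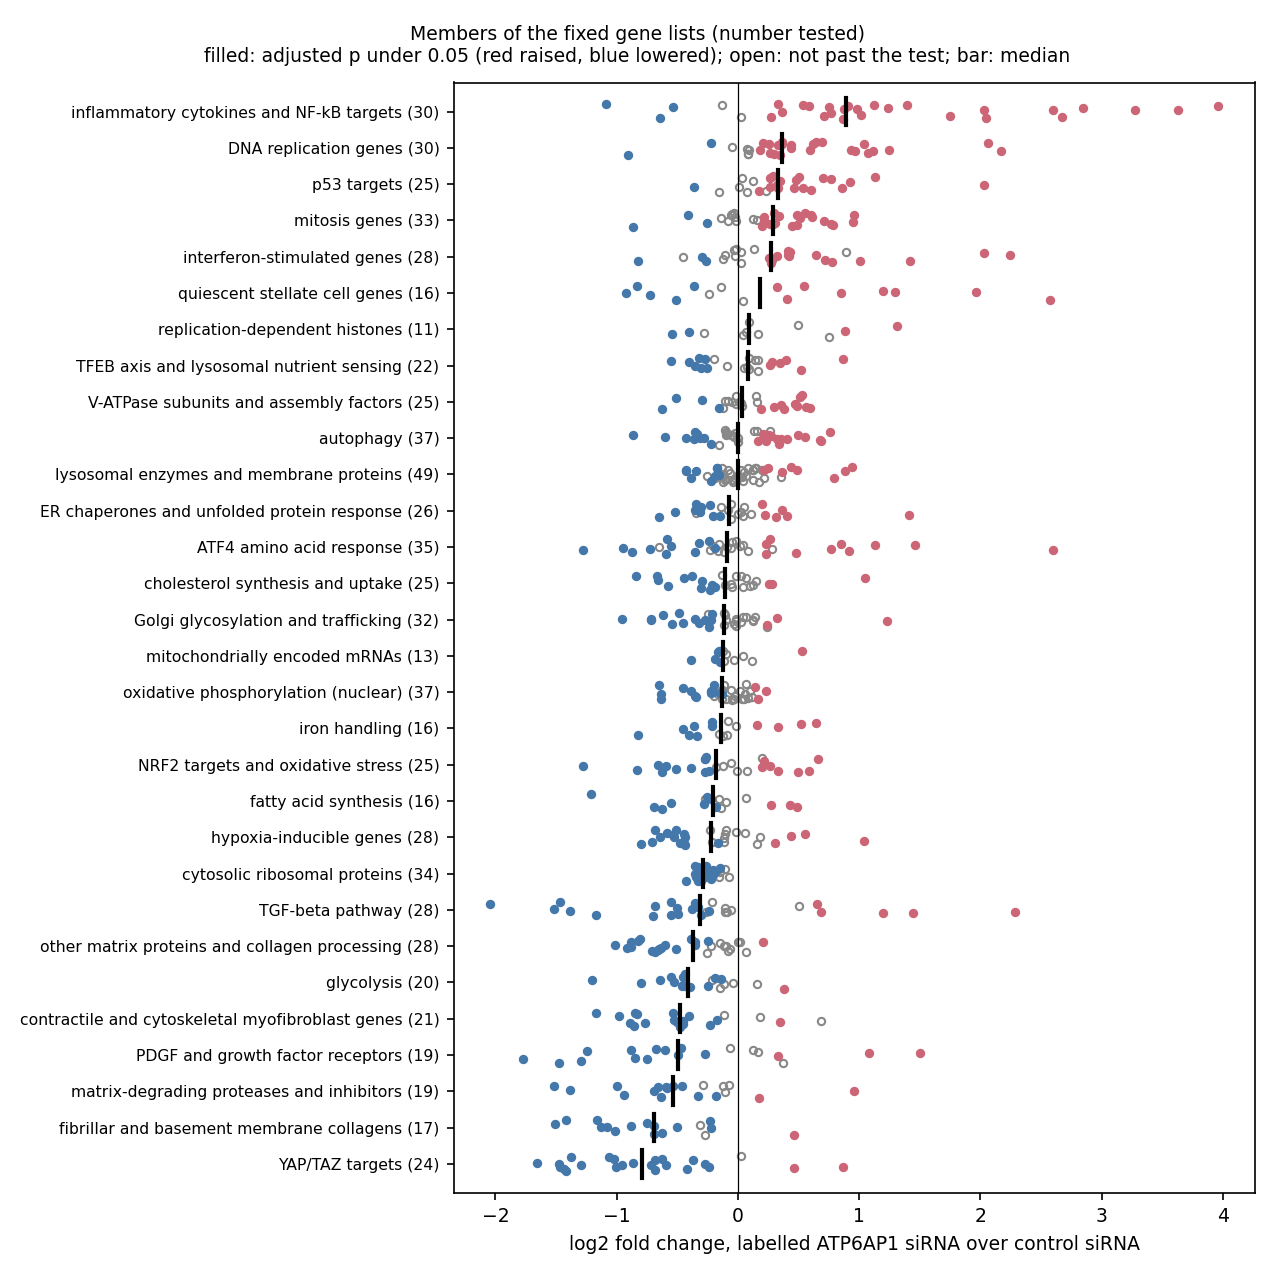
Log2 fold change (libraries labelled ATP6AP1 siRNA over control siRNA) of the tested members of each pathway and RNA quality list, with the number tested; filled points passed edgeR's test (red raised, blue lowered), open points did not, and black bars are medians. Medians ran from -0.79 for YAP and TAZ targets to 0.89 for inflammatory genes, relative to the scaling used, which moves the medians of lists near 0 across it when library size alone is used.

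Glycolytic genes were lower in 14 of 20, with SLC16A1 raised and 5 not past the test, and 2 raised and 15 lowered adjusted over the list alone (camera adjusted p = 0.000197, adjusted p = 0.346 with an estimated correlation). The hexokinases HK1 and HK2 both fell, HK2 by 0.64, LDHA by 0.79 and PKM by 0.55. Hypoxia-inducible genes were lower in 14 of 28, with PFKFB3, KDM3A, ANGPTL4 and EGLN3 raised and 10 not past the test (camera adjusted p = 0.0199, adjusted p = 0.486 with an estimated correlation). P4HA2 fell by 0.68, and EGLN1 by 0.58, the latter uncertain with 69.7% of its windows shared. Golgi glycosylation and trafficking genes were lower in 13 of 32, with COG4, GOLGB1 and MAN1A1 raised and 16 not past the test (camera adjusted p = 0.0491, adjusted p = 0.432 with an estimated correlation). FUT8 fell by 0.96, MAN2A1 and COG5 both by 0.72 and TMEM165 by 0.54. With the gene span trend removed, FUT8 was at -0.50, MAN2A1 at -0.45 and COG5 at -0.24. The Golgi call was lost under 9 alternatives, among them library size alone, where its median log2 fold change was 0.026 against -0.11 in the main test (camera adjusted p = 0.137), and the replicate block, where the median was -0.11 (0.0717). It was also lost without control replicate 1 (median -0.10, adjusted p = 0.0508), control replicate 3 (-0.069, 0.124), ATP6AP1 siRNA replicate 1 (-0.12, 0.0711) and ATP6AP1 siRNA replicate 3 (-0.10, 0.0523), over a range of adjusted p up to 0.432. The median gene span was 33.2 kb for glycolysis, 52.7 kb for hypoxia and 60.4 kb for the Golgi list.

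The lists closest to the V-ATPase did not pass camera. Of 25 tested V-ATPase subunits and assembly factors, 10 rose, 4 fell (ATP6V1E2, ATP6V0E1, ATP6V0E2 and ATP6V1B2) and 11 did not pass, and 11 rose and 4 fell adjusted over the list alone (camera adjusted p = 0.295, fry adjusted p = 0.0152, toward higher). ATP6V0B rose by 0.60, TMEM199 by 0.56 and ATP6V0A1 by 0.53, while ATP6V0E1 fell by 0.51. Of 49 lysosomal genes, 8 rose and 9 fell (camera adjusted p = 0.814), and the list's median (-0.00031) and mean (0.048) differed in sign. NEU1 rose by 0.94, LGMN by 0.79 and GUSB by 0.44, while LAMP1 had a log2 fold change of -0.042 (edgeR adjusted p = 0.593) and CTSD of -0.19 (0.0873), with 61.3% of its windows shared. CTSD passed as lower in 4 alternatives, among them without control replicate 1 (edgeR adjusted p = 0.0490). Autophagy genes rose in 14 and fell in 9 of 37 (camera adjusted p = 0.675), with GABARAPL1 at 0.69, SQSTM1 at 0.26 and ATG7 at -0.86 (-0.46 with the gene span trend removed). Genes of the TFEB axis and lysosomal nutrient sensing rose in 6 and fell in 7 of 22 (camera adjusted p = 0.766), with FLCN at 0.86 (31.5% of windows shared), TSC1 at 0.52, TFE3 at -0.41, and TFEB at 0.17 (edgeR adjusted p = 0.490).

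Cholesterol synthesis and uptake genes fell in 11 of 25 and rose in 3, HSD17B7, SC5D and TM7SF2 (camera adjusted p = 0.124, fry adjusted p = 0.00279, toward lower). The list passed camera once the trend on gene span (adjusted p = 0.00778) or on transcript length and GC content (adjusted p = 0.0448) was removed, over a range up to 0.511 across alternatives. HMGCS1 fell by 0.84, MSMO1 by 0.66 and INSIG1 by 0.58. Fatty acid synthesis genes fell in 8 of 16 and rose in 3, ACSS2, ACACB and GPAM (camera adjusted p = 0.0730, fry adjusted p = 0.000198, toward lower), with ELOVL6 at -1.21, FADS2 at -0.69, ACACA at -0.63 (-0.18 with the gene span trend removed) and SCD at -0.55. Iron handling genes fell in 7 of 16 and rose in 4, SLC39A14, NCOA4, HFE and SLC40A1 (camera adjusted p = 0.240, fry adjusted p = 0.00117, toward lower), with the reductase STEAP3 at -0.82, the ferritin chain FTL at -0.36 and FTH1, 41.3% shared, at -0.40.

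Genes of the ATF4 amino acid response rose in 10 and fell in 11 of 35 (camera adjusted p = 0.735; the median, -0.087, and the mean, 0.028, differ in sign), with ATF3 at 2.60, SLC3A2 at 1.46, DDIT3 at 0.92 and CEBPG at 0.85. ER chaperones and genes of the unfolded protein response rose in 6 and fell in 10 of 26, and 6 and 11 adjusted over the list alone (camera adjusted p = 0.408). The stress sensor ERN1 rose by 1.41 and XBP1 by 0.40, while CREB3L2 fell by 0.65 and ATF6 by 0.52 (-0.21 with the gene span trend removed). NRF2 targets rose in 7 and fell in 11 of 25, and 7 and 13 adjusted over the list alone (camera adjusted p = 0.256, fry adjusted p = 0.00232, toward lower), with SLC7A11 at -1.28, TXNRD1 at -0.83, NQO1 at -0.63 and SOD2 at 0.58. Nuclear genes of oxidative phosphorylation fell in 13 of 37 and rose in 3, UQCRC2, CYC1 and NDUFS3, or fell in 11 and rose in 1 adjusted over the list alone (camera adjusted p = 0.0626, fry adjusted p = 0.0404, toward lower). That list passed camera without control replicate 3 (0.0118), without ATP6AP1 siRNA replicate 3 (0.0471) and with the span trend removed (0.00346), over a range of adjusted p up to 0.640.

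Some measures of the libraries moved with the group beside these gene lists. Cytosolic ribosomal protein genes fell in 30 of 34 and rose in 0 (median log2 fold change -0.29, and -0.33 to -0.15 over alternatives; median span 5.32 kb; camera adjusted p = 3.51e-05, adjusted p = 0.561 with an estimated correlation). RPL23 fell by 0.43. The share of counts in mitochondrial rRNA was 0.155, 0.146 and 0.145% in the control libraries and 0.264, 0.318 and 0.319% in those labelled ATP6AP1 siRNA. MT-RNR2 rose by 0.97 and MT-RNR1 by 0.60. The 10 genes with most counts held 4.87 to 5.08% of the control libraries and 3.59 to 3.79% of the others. Mitochondrially encoded mRNAs rose in 1 and fell in 5 of 13 (camera adjusted p = 0.254), with MT-ND6 at 0.53 and MT-ND3 at -0.38 (-0.23 with the trend on transcript length and GC content removed). Replication-dependent histones rose in 2 and fell in 2 of 11 (camera adjusted p = 0.675), with H1-2 at -0.55 and H4C14, all of whose windows are shared, at 1.31.

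Markers of other liver and neural cells varied in level and in direction. The epithelial list, tested on 5 genes, had 2 lowered and 0 raised (camera adjusted p = 0.291, fry adjusted p = 0.0151, toward lower): KRT8 went from 285 to 198 CPM and KRT18 from 235 to 133, both uncertain with 39.2% and 35.3% of windows shared. Among hepatocyte markers, ALB had a mean of 0 CPM in the control libraries and 0.116 in the others, SERPINA1 fell from 8.05 to 5.02 CPM, TF, chosen after its values were seen, went from 2.70 to 3.48 CPM without passing the test, and CPS1 went from 27.2 to 22.8 CPM, a call lost in 3 alternatives, among them that without control replicate 1 (edgeR adjusted p = 0.118) and the removal of the gene span trend, which reversed its direction. The endothelial TIE1 and TEK went from 105 to 89.6 and from 14.8 to 12.2 CPM, calls lost in 7 and 11 of 16 alternatives. TIE1 was lost without control replicate 2 (edgeR adjusted p = 0.0906) or 3 (0.310, with the log2 fold change at -0.099 against -0.22) and ATP6AP1 siRNA replicate 2 (0.0714) or 3 (0.105). TEK was lost without control replicate 1 (0.154) or 3 (0.172) and ATP6AP1 siRNA replicate 1 (0.0804) or 3 (0.148), and both with the replicate block (0.0996 and 0.0905). The endothelial KDR, chosen after its values were seen, went the other way, from 2.40 to 6.81 CPM. CD68 and CD14, of macrophages, went from 61.2 to 57.1 and from 3.5 to 3.14 CPM without passing the test (91.9% of the windows of CD68 are shared), and the leukocyte marker PTPRC had means of 0.483 and 0.316 CPM. Of neural markers, SNAP25 went from 7.04 to 6.04 CPM without passing, though it passed without ATP6AP1 siRNA replicate 3 (edgeR adjusted p = 0.0400), and TUBB3 rose from 42.9 to 70.6 CPM, uncertain with 92.8% of its windows shared.

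The set calls rest on camera's preset setting, as none passed with an estimated correlation. Members varying together do not account for each loss. The estimated correlation was -0.025 both for p53 targets and for growth factors, below the preset 0.01. Their camera adjusted p still went from 7.24e-05 to 0.170 and from 0.0239 to 0.321. The estimated setting also takes its degrees of freedom from the few libraries, not from the genes, which makes it stricter. In each other changed list the estimated correlation was above the preset, which makes the preset p-values smaller. It ran from 0.025 for interferon-stimulated genes to 0.84 for ribosomal protein genes, with 0.40 for collagens, 0.32 for contractile genes and 0.28 for other matrix genes. Exons of 67 of the 159 genes that the rule names overlap a gene on the opposite strand, among them ACTA2, COL1A1, IL6, CCBE1, HAS2, ATP8B1, E2F8, CRIM1, SMAD3, TGFB1, TGFB2, TPM1, VIM, SPARC, LOX, CCN2, CDKN1A, IRF1 and NGFR, and their values are uncertain to that extent because the strand setting of the counting is not given in the sources used here.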

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

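The unrounded values and the removal of trends on gene span, or on transcript length and GC content, were chosen only after the data were seen. Between 6201 (adjusted p under 0.01) and 9088 (length and GC trend removed) genes changed, and 82.5 to 99.9% of the 8193 main calls were kept in direction across the 16 alternatives that refit the genes at the same threshold. Leaving out each library in turn gave 6863 to 8087. DESeq2 called 7415 and limma-voom 8163. With the replicate number as a block (replicate block), 7195 changed, 3619 raised and 3576 lowered, and 15 lists. Samples of the same number did not deviate together (correlations across genes -0.088, -0.029 and -0.10), and no sample correlated best with its own number. The values thus show no pairing by number, but they cannot tell whether samples of the same number were prepared together. ATP6AP1 was higher in each of the 16 alternatives, at log2 0.18 to 0.38, with a highest adjusted p of 0.0281.

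The count changed at least 2-fold moved from 1133 to 597 with 5 CPM in 3 libraries, where fewer genes were tested (11591), and reached 1463 at most. The count of changed lists moved from 16 to 0 with an estimated correlation, to 24 with fry, and to 15 to 17 otherwise. The estimated correlation allows for members varying together, and that setting also takes its degrees of freedom from the libraries, not the genes. CPS1 reversed, from -0.25 to 0.046, with the gene span trend removed (adjusted p = 0.662); the cause was not tested. Of 159 named genes, 150 kept their call in each alternative. Among the others, MT-CYB, MT-CO3 (uncertain, 30.6% of its windows shared), CPS1, TIE1 and TEK lost theirs in some, while FN1, CTSD (uncertain, 61.3% shared) and SNAP25 gained one. In simulated data of this depth and size, 44% of the smallest planted changes and 96% of 2-fold changes were recovered. Far fewer genes changed there than here, so these shares do not give the recovery in these data. Small changes were missed, so a gene not past the test is not shown to be unchanged.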

Other observations

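The families named by shared symbol stems, the comparison with random lists, the test of exchanged labels, the model with transcript length and GC content, and the removal of the gene span trend as an alternative were chosen only after the data or the results were seen. Genes were also grouped by the stem of their symbol, which gave 60 families of at least 20 tested members. In camera with the preset correlation and Benjamini-Hochberg adjustment, 8 differed, 3 raised (ZNF, RBM and KLHL) and 5 lowered (RPL, COL, MIR, RPS and ARHGAP), and none of the 8 passed with an estimated correlation (adjusted p = 0.414 to 0.801). With the gene span trend removed, the median log2 fold change went from -0.29 to -0.13 for ARHGAP and from -0.59 to -0.35 for COL. Zinc finger genes of the stem ZNF, most of them DNA-binding proteins, were the clearest: of 493 tested, 321 rose and 29 fell in the libraries labelled ATP6AP1 siRNA, whose target was not lower. Their median log2 fold change was 0.50 (0.51 with DESeq2's size factors, 0.64 with library size alone, 0.44 with the gene span trend removed), with an adjusted p of 1.50e-14 in camera and 0.414 with an estimated correlation. Among 10000 random lists of the same size matched on mean expression and gene span, the middle 95% of medians lay from 0.034 to 0.14. The highest was 0.19. Genes were drawn one by one, so that comparison does not cover members that vary together, and the family was singled out for it because of its values. RNA-binding motif genes (RBM) rose in 21 and fell in 2 of 38, and Kelch-like genes (KLHL) rose in 15 and fell in 5 of 24. MicroRNA host genes and precursors (MIR) fell in 12 and rose in 0 of 27.

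ATP6AP1 was not lower in the libraries labelled ATP6AP1 siRNA. An exchange of the groups' labels, with a depletion of at least 2-fold, would need a log2 fold change of 1 or more, and the value was 0.25 (95% interval 0.11 to 0.38). Reads from near-identical copies would need shared sequence, and 0% of its 50-base windows were shared. An exchange with a depletion of under 1.30-fold stays open, as do a depletion that had ended by the time of harvest, a loss of protein without a loss of mRNA, and an siRNA that did not act. Protein was not measured here and no biological explanation was tested, so whether the differences between the groups follow from ATP6AP1 is open too.

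The longest genes were lower, though the trend was not even (medians of -0.030 in the shortest decile and 0.14 around 13.8 kb): the longest decile by span (1298 genes, median 249 kb) had a median log2 fold change of -0.40 (bootstrap 95% interval -0.43 to -0.37; -0.39 with DESeq2's size factors, -0.26 with library size alone). The bootstrap resampled genes, which are not independent replicates, so its intervals do not measure the spread between libraries. With transcript length, GC content, exon number and mean expression in a linear model over 12972 protein-coding genes, which are not independent replicates, the slope per log10 of span was -0.34 (-0.36 to -0.31), against those properties as the whole cause, and the model took up 10.3% of the variance. Without the members of the matrix, contractile, TGF-beta, YAP and TAZ and growth factor lists, the decile's median was -0.39 (-0.42 to -0.36, 1274 genes). As 1274 of the 1298 genes were kept, the median could hardly have moved, so this was no real test. It shows only that the members are too few to make up the decile's shift. A difference in RNA quality stays open, beside the higher share of mitochondrial rRNA, and so does a hypothesis that transcription through long genes was slower or ended earlier; neither was tested, and the first is confounded with the groups.

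The collagen, other matrix, contractile and YAP and TAZ lists were lower in camera with the preset correlation, with a median over their 90 members of -0.61 (bootstrap 95% interval -0.70 to -0.46), but none passed with an estimated correlation (adjusted p = 0.396, 0.396, 0.396 and 0.321). Bootstrap intervals of these medians resample genes, which vary together, so they do not measure the spread between libraries. With each library's trend on gene span removed the median was -0.57 (-0.63 to -0.42). The median of all protein-coding genes reached only -0.40 even in the longest decile, so the removal could hardly have taken up the whole shift. It shows only that the trend is too small to be the whole cause. An off-target effect through the seed of a transfected siRNA, whose sequence is not known here, was searched for over 15955 heptamers in the 3' UTRs of 12781 genes: the heptamer most strongly tied to lower fold changes went with -0.083 (-0.11 to -0.056), and 17.4% of the lowered members with a 3' UTR carried it (12 of 69; 9.32 to 28.4%) against 15.7% of the genes searched. The bars set beforehand for the explanation were not reached, neither carriers in over 50% of these members nor an absolute t over 1.5 times that of the strongest heptamer of opposite sign (t of -5.999 against 6.209). The bar of 50% was high for any 1 heptamer, so missing it says little against a seed. No heptamer (0) went with a drop of 0.1 or more at a Bonferroni-adjusted p under 0.05, which meets a bound set beforehand for setting it aside, but the interval of the strongest reaches -0.11 and the share's upper bound of 28.4% lies above the other bound of 25%, so a seed acting on fewer of these genes, or through others, stays open, as does an effect of what the label names, for which ATP6AP1 gives no measured depletion.

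The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Each other split mixes both groups, so part of the real difference remains between its sides and part lies within them. The real split was the 1 with as many genes (8193; highest other 0 in edgeR, 60 to 393 at an unadjusted p under 0.05) and the 1 with as many lists (16; highest other 12).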
